A study of Phaeodactylum tricornutum with 16 samples.

How the data were processed

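Total RNA of the diatom Phaeodactylum tricornutum was measured on 16 Agilent arrays of 1 colour (Cy3). Per the labels, axenic cultures had been grown in cycles of 16 h light and 8 h dark, and samples were taken at 8 time points with 2 replicates each, which the labels call biological. Harvests ran in the order 0.5, 6, 10.5 and 15.5 h light, then 0.5, 4 and 7.5 h dark, and last 3 h light of the following light period. Group and replicate number were taken from the sample titles. The labels do not say which culture gave which sample.

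Per the file headers, the deposited scanner files hold spot intensity values extracted with Agilent Feature Extraction. The processed signal had been background-subtracted and detrended within each array, with no scaling between arrays. The deposited value table holds intensity values on a linear scale, rounded to whole numbers. On each array they rank the probes as the raw median spot signal does (Spearman correlation of 1 on all 16 arrays), and the array medians lie between 3998 and 4012. The 5th, 25th, 75th and 95th percentiles of the table differ between the arrays by factors of at most 1.022, against 1.629 to 2.79 for those of the raw median signal. The submitters' processing notes name limma 3.2.3 and R 2.10.1; the step that made the table is not given in the sources used here. No direction has to be known, because the table holds levels and not ratios.

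Each array carried 45220 spots, of which 1417 were control spots and left out. The other 43803 spots each held a different probe of 60 bases. Over all arrays 208 spots flagged as outliers by the scanner software were set to missing, and saturated spots (0 or 1 per array) were kept. Between 95.82% and 98.38% of the probes were well above background per array. A probe entered when it was well above background on both arrays of at least 1 group, which kept 42991 probes and removed 812. The number of arrays, 2 per time point, limits the precision.

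The main values were log2 of the processed signal minus the 75th percentile of each array. A model with 8 group means (8 residual degrees of freedom) was fitted per probe over all 16 arrays with limma 3.58.1 in R 4.3.3, so that all groups shared the estimate of spread. Probes were called at a Benjamini-Hochberg adjusted p below 0.05, by the moderated F-statistic over the 8 groups and by the moderated statistic of 5 pairwise comparisons and of the mean of the 5 light groups minus the mean of the 3 dark groups. Signature groups were tested with camera at a preset correlation of 0.01, adjusted over 72 tests, and again with a correlation estimated from the residuals and with fry. The comparisons, the model and the alternatives were chosen before the data were examined, except scaling on the spike-in spots, which was added after the data had been seen.

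The arrays name their probes by design numbers only. The reference table of 10398 RefSeq genes matched 0 of these names, so the unit counted here is the probe, and no probe was assigned to a gene. The 24 lists of gene names fixed in advance, and the choice of genes by product name, could therefore not be applied. In their place the 60 bases of each probe were translated in the 3 forward frames with Biopython 1.88 in Python 3.11.15 and searched for 88 protein signatures, written down from general knowledge after the probes had proved unnamed and before the signal of any group of probes was read. A signature was a short conserved motif, or a conserved protein with which a translated probe of up to 20 residues shared at least 12 or 13 residues. The opposite strand served as control. A signature was used when its hits there were at most 25% of its forward hits, and a group when it held at least 3 probes. This left 31 signatures with 120 probes in 12 groups. They are not lists fixed in advance, and a probe that carries a signature is not thereby a known gene. For a signature with 1 forward hit the rule asked only for 0 opposite hits, which hardly guards against a chance hit. Among these were ribonucleotide reductase, the HSP70 and HSP90 end, isocitrate or isopropylmalate dehydrogenase, acyl-CoA dehydrogenase and the DEAD-box helicase. Malate dehydrogenase, which was not used, had 1 hit on each strand. Probe numbers and sequences were reported for the 2 largest rises and the 2 largest falls over the 5 pairwise comparisons, among probes above background in both groups whose arrays did not overlap, a rule set before their values were seen.

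Probes with neighbouring design numbers had a median correlation over the 16 arrays of 0.953 (39080 pairs), against 0.0265 for random pairs. Counts of probes are therefore not counts of genes.

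The replicate numbers are shared by all time points. The deviations of same-numbered arrays from their group means correlated at 0.391 to 0.862 over the 28 pairs of time points (median 0.639). Same-numbered arrays thus shared a deviation, whether through culture, slide or scan day. The main model did not hold the replicate number, which was an alternative. All arrays of replicate 1 were scanned on another day than those of replicate 2. The arrays lay on 4 slides of 4 arrays. The first 4 harvests of a replicate shared a slide, and so did its last 4. Each slide held 1 array per group, so no test within a slide could be made. The slide was put into the model as a random block instead, and also as a fixed block where both groups lay on the same slides, and the differences within each replicate number were computed for the signature groups. Replicate arrays correlated at 0.9407 to 0.9772, and 0 probes had identical values in both replicates of a group.

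The alternatives were normexp background correction (offset 50) of the mean signal, quantile normalisation, the authors' table, no filter or a strict filter on dim probes, the replicate number or the slide as a block, a variance prior with trend and robust estimation, a fold change of at least 2 as a further threshold, only the arrays compared, each array left out in turn, other choices of light groups, and scaling on 6 spike-in probes (192 spots).

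The model was tested on simulated data with the spread of the real arrays, with 200 of 42815 probes changed. Of the probes changed by 2 on the log2 scale, 38% were recovered for the F-test, 65% for 3 h light against 7.5 h dark, 63% for 0.5 h light against 7.5 h dark, 56% for 15.5 h light against 0.5 h light, 57% for both comparisons with 0.5 h dark and 97% for light against dark. At a change of 1 these shares were 0%, 11%, 13%, 8%, 11% after lights off, 15% through the dark period and 68%. The adjusted threshold depends on the share of probes that changed, and the real F-test called 54.5%. The simulated shares therefore do not measure the recovery behind the larger counts. Of 100 simulated sets of 20 probes, camera called all 10 that had been shifted and 0 of the others. The noise was drawn independently per probe and the sets at random, whereas real groups had estimated correlations of up to 0.709. This result therefore says nothing on false calls among correlated probes.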

Results

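RNA levels in Phaeodactylum tricornutum, a marine diatom with a sequenced genome, were followed through a cycle of 16 h light and 8 h dark. Samples came from 5 time points in the light (0.5, 3, 6, 10.5 and 15.5 h after lights on) and 3 in the dark (0.5, 4 and 7.5 h after lights off), with 2 replicates each, 16 arrays in all. The title of the series places the study in carbon fixation, storage and utilisation under light/dark cycles. The median processed signal per array ran from 2449 to 5873, against 5.76 for the negative control spots, and replicate arrays correlated at 0.9407 to 0.9772. The probes carry no gene names, so groups of probes are described by the protein signature that their translated sequence carries, and a count of probes is not a count of genes.

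Much of the measured transcriptome varied with the time of day. Of 42991 probes, 23414 (54.5%) differed between at least some of the 8 time points (limma F-test, adjusted p below 0.05), with a median range between the highest and the lowest group mean of 1.78 on the log2 scale. The range was at least 3 on the log2 scale, or 8-fold, for 3898 of them. The highest group mean fell at 0.5 h light for 5499 probes (23.5%), with the same peak in both replicates for 4085 of them, and at 0.5 h dark for 4047 (17.3%), with the same peak in both for 2038. Of the 4047 probes 0 were called higher at 0.5 h dark than at 15.5 h light (limma, 83 at an unadjusted p below 0.05), so the peak at 0.5 h dark was not set apart from the time point before it. Of the 5499 probes 913 were called higher at 0.5 h light than at 7.5 h dark, and the others were not set apart from 7.5 h dark either. Only 1325 probes (5.66%) peaked at 4 h dark. Among the same probes 3173 peaked at 0.5 h dark and 4598 at 15.5 h light with normexp, and 9799 at 0.5 h dark with spike-in scaling. Lowest levels were most frequent at 3 h (4493 probes) and 6 h light (4379 probes), but with quantile normalisation at 0.5 h light (4036 probes). With spike-in scaling 11256 of the same probes were lowest at 3 h light, 3724 at 7.5 h dark and 1119 at 6 h light. Only 31 then peaked at 3 h light and 216 at 7.5 h dark. At these 2 time points the replicates differed in the spike-in signal relative to the 75th percentile. It was 0.639 and -0.522 on the log2 scale in replicates 1 and 2 of 3 h light, and 0.167 and -0.694 in those of 7.5 h dark. Both replicates gave the same peak time for 12705 of the called probes (54.3%), and the same or the next time point for 20149 (86.1%). With arrays scaled on spike-in spots, an alternative chosen after the data had been seen, 14252 probes were called. The replicate block, in contrast, called more probes than the main model.

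**Figure D1:**
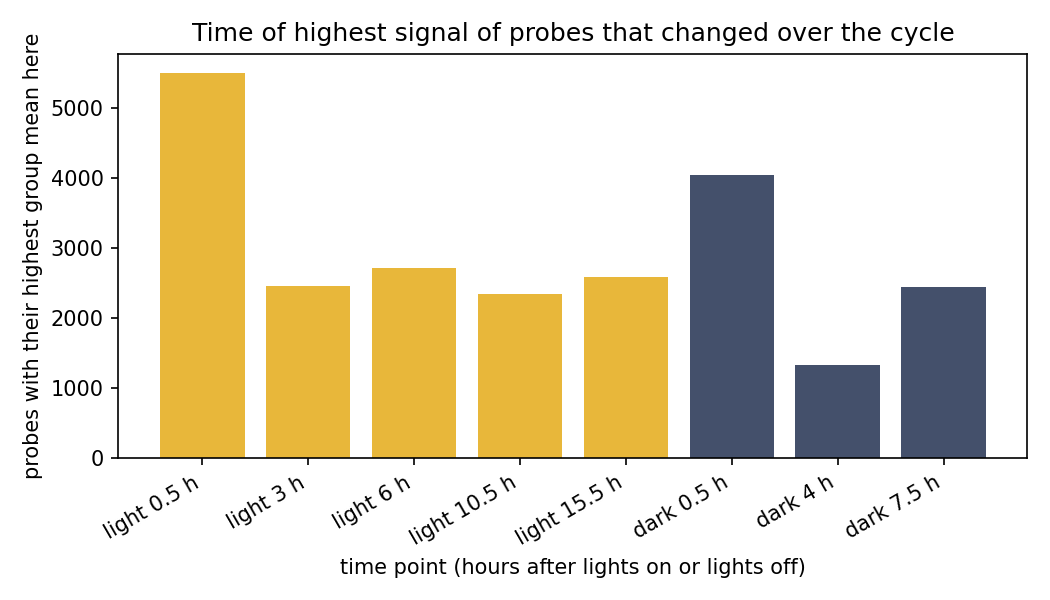
Number of probes (vertical axis) with their highest group mean at each time point (horizontal axis, hours after lights on or lights off), among the 23414 probes that changed over the cycle; yellow bars are light and dark blue bars dark time points. The tallest bars stand at 0.5 h light (5499 probes) and 0.5 h dark (4047 probes), and the lowest at 4 h dark (1325 probes).

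Groups of probes differed in their time of day. Of 20 probes with signatures of cytosolic ribosomal proteins, the building blocks of the translation machinery, 17 changed over the cycle, and 15 of these peaked at 3 h light. Their mean stood at 0.55 ± 0.13 (SD, n = 2) above the cycle mean on the log2 scale at 3 h light and at -0.87 ± 0.44 at 10.5 h light. The low at 10.5 h light held under each scaling (-0.87 to -0.91), but the peak at 3 h light did not. With quantile normalisation the mean was 0.26 at 3 h and 0.22 at 0.5 h light, with 7 of the 17 peaking at 3 h light (8 in the authors' table), and with spike-in scaling it was highest at 0.5 h dark (0.45), with 0 of the 17 peaking at 3 h light. All 4 probes of elongation factor 1-alpha, which brings tRNAs to the ribosome, also changed and peaked at 3 h light. Their mean was highest at 0.5 h light with quantile normalisation (0.31), in the authors' table (0.36) and with spike-in scaling (0.42). Core histones, the proteins around which DNA is wound, had their highest levels late in the light: 16 of 20 probes changed, 10 with a peak at 10.5 h and 6 at 15.5 h light. The group mean rose from -0.67 ± 0.37 at 0.5 h light to 0.58 ± 0.19 at 15.5 h light and stood at -0.82 ± 0.46 at 7.5 h dark, the lowest time point under each scaling. With spike-in scaling the mean was highest at 0.5 h dark (0.96), where 15 of the 16 then peaked. All 4 alpha-tubulin and both beta-tubulin probes changed and peaked at 15.5 h light, while 0 of 5 actin probes passed the F-test. Of these 6 tubulin probes 4 peaked at 0.5 h dark with quantile normalisation and in the authors' table, and all 6 with spike-in scaling.

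All 6 probes of glyceraldehyde-3-phosphate dehydrogenase (GAPDH), an enzyme of glycolysis and, in the chloroplast, of carbon fixation, changed, with peaks at different times of the light period. In 4 of them the peak fell at 0.5 or 6 h light and the lowest level at 0.5 h dark, with ranges of 4.04 to 5.64 on the log2 scale. The other 2 peaked at 10.5 h light and were lowest at 0.5 h light, with ranges of 4.12 and 4.15. In the authors' table and with spike-in scaling these 2 peaked at 15.5 h light, and with quantile normalisation 1 of them did. Of the other 4, 1 peaked at 3 h light with quantile normalisation, with normexp and in the authors' table. Among 7 probes with the helix signature of light-harvesting proteins, which bind the pigments of the photosynthetic antenna, 6 changed, with peaks at 0.5, 6 or 10.5 h light (2 probes each). Their mean was 0.74 ± 0.02 (SD, n = 2) at 6 h light, the highest time point under each scaling, and -0.59 ± 0.12 at 0.5 h dark.

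**Figure D2:**
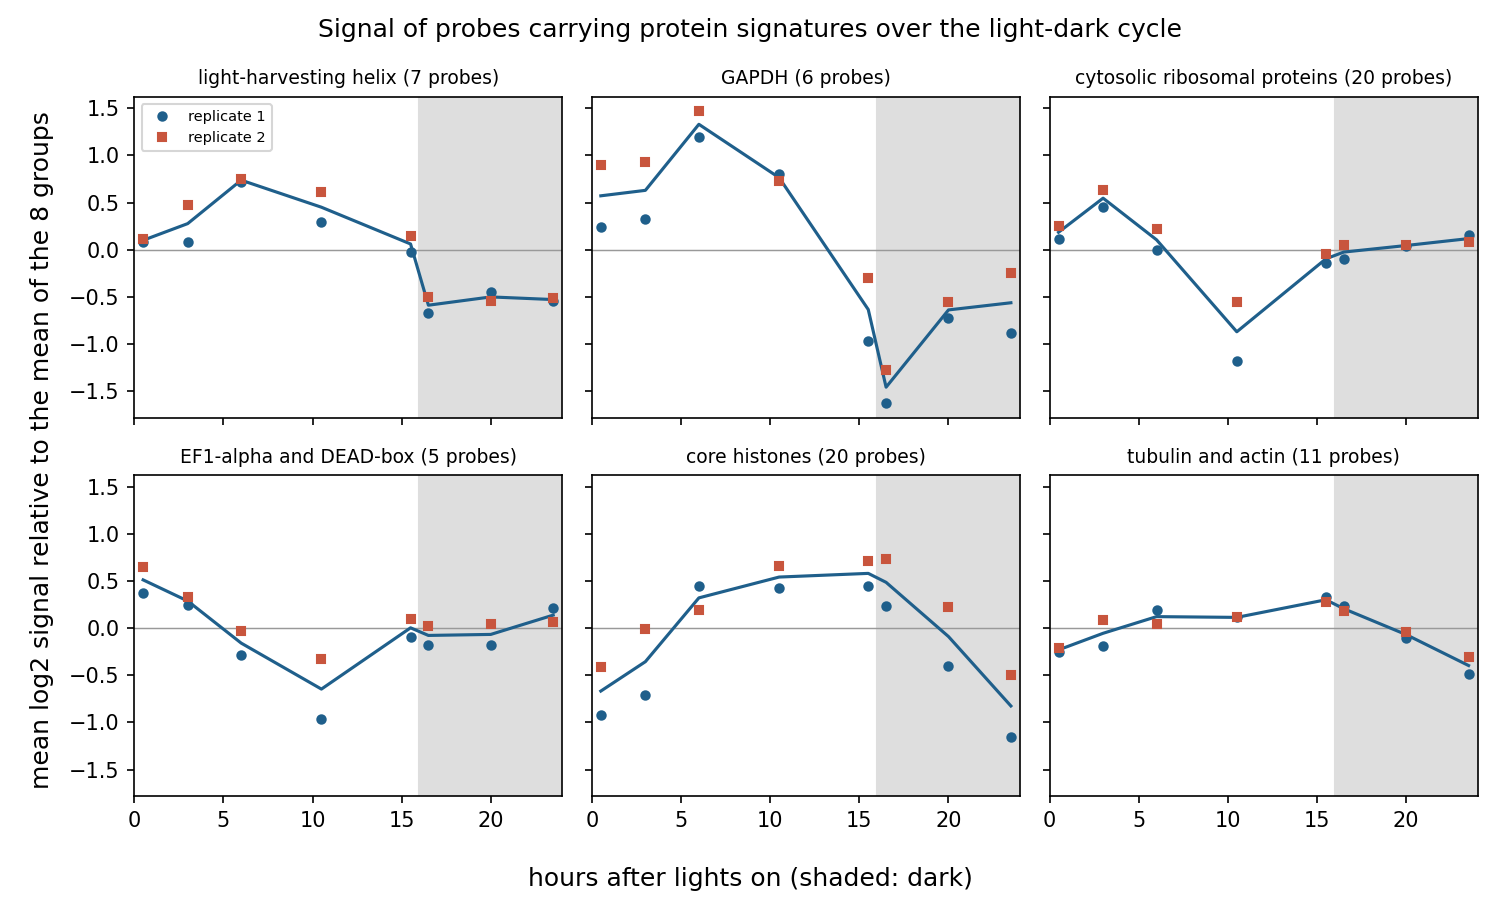
Mean log2 signal relative to the mean of the 8 groups (vertical axis) against hours after lights on (horizontal axis; dark period shaded) for 6 groups of probes named by protein signature; points are the 2 replicates and lines join the group means. The 3 h light samples were harvested last, in the following light period. Ribosomal protein probes were lowest at 10.5 h light (-0.87) and highest at 3 h light (0.55), a peak that lay at 0.5 h dark with spike-in scaling and hardly above 0.5 h light with quantile normalisation (0.26 and 0.22); histone probes were lowest at 7.5 h dark (-0.82), and light-harvesting probes highest at 6 h light (0.74).

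The 2 largest rises and the 2 largest falls over the 5 pairwise comparisons, among probes above background in both groups, belonged to 4 probes with neighbouring design numbers. CUST_16146_PI255610003 (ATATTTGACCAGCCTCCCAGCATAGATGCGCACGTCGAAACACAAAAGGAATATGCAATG) rose by 9.56 ± 0.44 (SE) on the log2 scale between 0.5 and 7.5 h dark, and CUST_16148_PI255610003 (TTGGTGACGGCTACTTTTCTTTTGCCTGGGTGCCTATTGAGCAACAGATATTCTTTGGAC) by 9.55 ± 0.46, both with an adjusted p of 4.15e-06. Between 0.5 and 15.5 h light CUST_16147_PI255610003 (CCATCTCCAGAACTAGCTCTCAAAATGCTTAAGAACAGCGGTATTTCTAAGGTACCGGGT) fell by 9.39 ± 0.55 and CUST_16149_PI255610003 (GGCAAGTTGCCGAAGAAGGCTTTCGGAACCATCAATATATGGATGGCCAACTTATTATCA) fell by 9.16 ± 0.49, with adjusted p of 1.46e-06 and 8.27e-07. The size of these falls depended on the processing: the changes were -5.63 and -5.62 with normexp and -7.76 and -7.68 in the authors' table. Both alternatives also start from another signal of the spots, so the part of the background correction was not tested alone. The rises were 8.09 and 8.05 with normexp and 8.07 and 7.93 in the authors' table. Both falling probes were well above background on both arrays of each group compared, but on 15 and 14 of all 16 arrays. The probes given for their rises also fell across the light period. Between 0.5 and 15.5 h light the change was -8.93 for CUST_16146_PI255610003 and -9.06 for CUST_16148_PI255610003. The files pair none of the 4 with a gene.

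The first pairwise comparison set 3 h light against the end of the night, 7.5 h dark. Ribosomal protein probes were higher by a mean of 0.43 on the log2 scale (0.30 in replicate 1, 0.56 in replicate 2; 19 of 20 probes positive), core histones by 0.47 (17 of 20), tubulin and actin by 0.34 (10 of 11) and GAPDH by 1.19 (4 of 6). Single probes that rose included both beta-tubulin probes (mean 0.99), 2 of 4 of elongation factor 1-alpha (mean of the 4, 0.53), both of ribosomal protein L23 (0.74), 4 of 6 of GAPDH, 1 of 6 of histone H2A and 1 of 7 of light harvesting (3.12). Of 16 probes with the catalytic loop of protein kinases 7 fell and 0 rose. The camera test gave adjusted p of 0.000161 for the ribosomal, 0.0135 for the histone, 0.0241 for the cytoskeleton and 0.0151 for the GAPDH probes, and with an estimated correlation adjusted p = 0.73, 0.885, 0.547 and 0.657. With the replicate block the light-harvesting group passed too (mean 0.81, adjusted p of 0.0366 in place of 0.0645), as it did with the slide as a fixed block (0.0306), but adjusted p = 0.547 with an estimated correlation. The replicate block also raised the number of single probes that rose to 8 of 20 ribosomal, 6 of 20 histone and 3 of 7 light-harvesting probes. Of the 21 probes of the signalling group, which holds the kinase probes, 2 rose and 9 fell with it, in place of 0 and 7.

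Over all probes, 8388 differed between 3 h light and 7.5 h dark, 2876 higher and 5512 lower (34.3% higher). The share higher was 48% with quantile normalisation, 47.7% in the authors' table and 22.1% with spike-in scaling, which called 1509 probes. The median over all probes stood at -0.16 on the log2 scale, at -0.01 after quantile normalisation and at -0.48 with spike-in scaling. None of the 4 group shifts passed with quantile normalisation. The ribosomal and cytoskeleton means were then 0.08 and 0.06 (adjusted p of 0.654 and 0.973; 0.08 and 0.04 in the authors' table), while the histone and GAPDH means were 0.41 and 1.02 (adjusted p of 0.158 and 0.142). With spike-in scaling the ribosomal, histone and cytoskeleton means were 0.11, 0.15 and 0.02. With the replicate number as a block 15132 probes were called, and with the slide as a fixed or random block 16441 and 15768. The cytoskeleton shift had an adjusted p of 0.0647 with the random block, and 0.212 with spike-in scaling. Spike-in spots stood at 0.64 and 0.17 on the log2 scale relative to the 75th percentile in replicate 1 of 3 h light and of 7.5 h dark, against -0.52 and -0.69 in replicate 2. Leaving out replicate 1 or 2 of 7.5 h dark left 2505 and 3710 probes, and leaving out replicate 1 of 3 h light 2808. The histone (means 0.15 and 0.12, adjusted p of 0.317 and 0.32) and cytoskeleton shifts (means 0.25 and 0.20, adjusted p of 0.111 and 0.102) were lost without replicate 1 of 7.5 h dark or replicate 2 of 3 h light, and the GAPDH shift (0.0917) without the former. The histone mean was 0.79 and 0.82 without replicate 2 of 7.5 h dark or replicate 1 of 3 h light.

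The second comparison asked what differed 0.5 h after lights on from 7.5 h dark, samples that lay on different slides. The 0.5 h light samples were harvested first, before the dark period that was sampled at 7.5 h. A rise or fall here is thus a difference between these time points, not a course followed from dark into light. A probe with the cyclin box rose, and both cyclin box probes together averaged 1.60 higher. The box is a fold of cyclins, of which some drive the cell division cycle. In light against dark 1 of these probes was called higher (0.315) and 1 lower (-1.27). The third probe carried the end of the small subunit of ribonucleotide reductase, which makes DNA precursors (0.76, not past the threshold). The group of 3 probes, called division probes by signature alone, had a mean of 1.32 (1.13 and 1.51 in replicates 1 and 2). Of 6 GAPDH probes 3 rose, and the other 3 had changes of 0.61, -1.23 and -1.26, not past the threshold. The mean of the 6 was 1.13 (1.12 and 1.15 in replicates 1 and 2). Light-harvesting probes went both ways: 1 of 7 rose by 4.58 ± 0.51 (SE) on the log2 scale, the largest change of that group, and 1 fell by 1.21 ± 0.24 (2 and 2 with the replicate block). The ribosomal protein (mean 0.07) and histone probes (0.16) had 0 of 20 called each, or 0 and 1 with the replicate block (lowest adjusted p of the histone signatures 0.17).

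Camera gave adjusted p of 0.0477 for the 3 division probes and 0.034 for GAPDH, and with an estimated correlation adjusted p = 0.657 and 0.71. With the replicate block they were 0.0537 and 0.0576, with quantile normalisation 0.075 and 0.0939, and with spike-in scaling 0.184 and 0.0891. In all 4848 probes differed, 1773 higher and 3075 lower (36.6% higher; 48.6% of 1073 probes with spike-in scaling, where the median over all probes was 0.49 on the log2 scale). The replicate block raised the count to 10183, the 4 arrays compared alone gave 1678, and without replicate 2 of 0.5 h light it was 2060, without replicate 1 or 2 of 7.5 h dark 1890 and 2284. The GAPDH shift had an adjusted p of 0.183 and 0.151 without replicate 2 of 0.5 h light or replicate 1 of 7.5 h dark, and 0.0747 and 0.0748 without either 6 h light array. The division shift lost its call without replicate 2 of 0.5, 3 or 10.5 h light, either array of 15.5 h light or 4 h dark, or replicate 1 of 0.5 or 7.5 h dark (adjusted p of 0.0504 to 0.147).

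Across the light period, from 0.5 to 15.5 h, core histone probes rose by a mean of 1.25 on the log2 scale (1.38 and 1.12 in replicates 1 and 2), with 14 of 20 probes called and all 20 positive. H2B (mean 1.73, 3 of 4 rose) and H2A (1.54, 6 of 6) moved most, H4 by 0.99 (4 of 4) and H3 by 0.81 (1 of 6). The tubulin and actin probes rose by 0.53 on average (0.58 and 0.48 in replicates 1 and 2). All 4 alpha-tubulin probes (0.97) and 1 of 2 beta-tubulin probes were called, and 0 of 5 actin probes. The ribonucleotide reductase probe rose by 1.68 (adjusted p of 0.0274). GAPDH probes split: 4 fell (changes of -3.09 to -4.24) and 2 rose by 3.95 each, so that the group's mean (-1.21) describes neither part, and its median (-3.47) lies among the falling probes. Camera gave this group an adjusted p of 0.0946. Light-harvesting probes split too, 3 rising and 2 falling.

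Camera gave an adjusted p of 2.53e-05 for the histones and 0.0379 for tubulin and actin, and with an estimated correlation adjusted p = 0.734 and 0.607. The shift of tubulin and actin had an adjusted p of 0.0671 with the replicate block, 0.0562 and 0.204 with the slide as a fixed or random block, 0.0888 with quantile normalisation, 0.267 with spike-in scaling and 0.114 with normexp. It had 0.123, 0.0751 and 0.0533 without replicate 1 of 0.5 h light, replicate 2 of 15.5 h light or replicate 1 of 7.5 h dark. Of all probes 10893 differed, 5760 higher and 5133 lower, 602 and 697 of them at least 8-fold. With the slide as a fixed or random block 17293 and 16567 were called, with spike-in scaling 4208, with the arrays compared alone 5922 and without replicate 1 of 15.5 h light 6657. The median over all probes was -0.01 on the log2 scale and 0.14 with normexp.

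Few probes differed 0.5 h after lights off from 15.5 h light, samples harvested in direct succession but placed on different slides. All 6 GAPDH probes were lower at 0.5 h dark than at 15.5 h light, with a mean change of -0.82 on the log2 scale (-0.66 and -0.98 in replicates 1 and 2), and 6 of 7 light-harvesting probes were lower (mean change -0.65; -0.65 in both replicates), although 0 of these 13 probes passed alone (1 light-harvesting probe with the replicate block). As groups, both passed as lower with the preset correlation (camera, adjusted p of 2.53e-05 each). With an estimated correlation adjusted p = 0.523 for GAPDH and 0.0968 for light harvesting. The fry test gave adjusted p of 0.096 for GAPDH and 0.011 for light harvesting. The light-harvesting mean was -0.42 with spike-in scaling and the GAPDH mean -0.49 without replicate 2 of 15.5 h light, both still past the threshold. The histone (mean change -0.10), cytoskeleton (-0.09) and ribosomal protein probes (0.07) had 0 members called. Over the whole array 57 probes passed, 7 higher and 50 lower, all at least 2-fold.

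That count depended on the model and on single arrays. It was 254 with the replicate block, 27 with the slide as a random block, 156 with normexp (1.28% higher, in place of 12.3%), 0 with only the 4 arrays compared (limma, 2087 at an unadjusted p below 0.05) and 0 with spike-in scaling (520 at an unadjusted p below 0.05). These compare with 1901 at an unadjusted p below 0.05 in the model as reported. The median over all probes was 0.06 on the log2 scale, -0.06 with normexp and 0.29 with spike-in scaling. Leaving out an array gave 3 probes without replicate 2 of 15.5 h light or of 0.5 h dark, 4 without replicate 1 of 0.5 h dark, 9 without any array of 4 or 7.5 h dark, 19 without either of 3 h light and 26 without either of 10.5 h light.

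Through the dark period, from 0.5 to 7.5 h, core histone probes fell by 1.31 on the log2 scale on average (mean change -1.38 and -1.24 in replicates 1 and 2), with 11 of 20 called and all 20 negative. H2B fell by 1.87 (4 of 4), H2A fell by 1.67 (6 of 6), and H3 (mean change -0.96) had 1 of 6 and H4 (-0.74) 0 of 4 probes called. With the replicate block 15 of the 20 histone probes were called lower, and 6 of the 11 tubulin and actin probes in place of 5. Both beta-tubulin probes fell (mean change -1.42), as did 3 of 4 alpha-tubulin probes (-0.85) and the ribonucleotide reductase probe (-2.36, adjusted p of 0.00802), while 0 of 5 actin probes passed. The GAPDH probes that had fallen during the light rose, by 1.94 to 2.99, and the other 2 fell (-2.26 and -2.31). Light-harvesting probes had a mean change of 0.06, with 1 of 7 rising (0.88); with the replicate block 3 rose and 1 fell.

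Camera gave adjusted p of 6.21e-08 for the histones, 0.00757 for tubulin and actin and 0.0379 for the 3 division probes (mean change -1.52). With an estimated correlation adjusted p = 0.657, 0.523 and 0.657. That correlation was 0.709 for the histone, 0.0741 for the tubulin and actin and 0.494 for the division probes, against the preset 0.01. The division shift had an adjusted p of 0.0573 with quantile normalisation, 0.232 with spike-in scaling, and 0.0508 and 0.0564 without replicate 2 of 0.5 h light or replicate 1 of 7.5 h dark. The cytoskeleton shift had an adjusted p of 0.069 with spike-in scaling, under which the histone, cytoskeleton and division means were -2.15, -1.45 and -2.36. In all 6396 probes differed, 3003 higher and 3393 lower (47% higher; 13.6% of 4030 with spike-in scaling, where the median over all probes was -0.83 on the log2 scale). The count was 10915 with the replicate block, 11812 and 11296 with the slide as a fixed or random block, and 2724, 3415 and 2625 without replicate 1 or 2 of 0.5 h dark or replicate 1 of 7.5 h dark.

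Averaged over the light and the dark time points, the means of the GAPDH, light-harvesting and, by less, core histone probes stood higher in the light than in the dark. GAPDH probes were higher by a mean of 1.42 on the log2 scale (1.40 and 1.44 in replicates 1 and 2), with 4 of 6 called higher and the other 2 at -0.19 and -0.21. Light-harvesting probes were higher by 0.86 (0.79 and 0.94; all 7 positive, 4 called), 1 of them by 2.21 ± 0.26 (SE). Camera gave adjusted p of 0.000798 and 0.00097, and with an estimated correlation adjusted p = 0.547 and 0.175. The histone shift was 0.23 (adjusted p of 0.034; adjusted p = 0.885 with an estimated correlation), with 1 of 20 probes called, or 6 with the replicate block (adjusted p of 0.0159). The shift was smaller and lost its call with quantile normalisation (mean 0.13, adjusted p of 0.515), in the authors' table (0.13, 0.518) and with spike-in scaling (0.05, 0.0828). It lost its call at about the same size with normexp (0.22, 0.114) and with the slide as a random block (0.23, 0.0835). It was also lost without replicate 2 of 0.5, 3 or 10.5 h light, replicate 1 of 6 h light or replicate 1 of any dark time point (means 0.12 to 0.20, adjusted p of 0.0545 to 0.177). Over all probes 16564 differed, 5743 higher and 10821 lower in the light (34.7% higher; 45.3% with quantile normalisation, 45.4% in the authors' table, 24% of 6761 with spike-in scaling), of which 1813 and 1949 at least 2-fold.

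The median over all probes in that comparison was -0.13 on the log2 scale, -0.04 with quantile normalisation and -0.31 with spike-in scaling. With the slide as a random block 8804 probes were called, and with time points as replicates in 2 groups 1901. Most of the light time points lay on other slides than the dark ones; 3 h light, which shared their slides, gave 16472 probes against the 3 dark groups.

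Of the 72 tests of 12 groups 16 passed with the preset correlation, 14 with the replicate block and 0 with an estimated correlation (6 at an unadjusted p below 0.05; camera, lowest adjusted p = 0.0968). The estimated correlation was 0.709 for the histone, 0.545 for the ribosomal, 0.494 for the division and 0.45 for the GAPDH probes. It was 0.0741 for tubulin and actin and 0.0149 for light harvesting. Where it lay far above the preset 0.01, the preset test treated correlated probes as nearly independent. For light harvesting it lay near the preset. Yet its camera adjusted p went from 2.53e-05 to 0.0968 after lights off, and from 0.00097 to 0.175 in light against dark. The size of the correlation alone therefore does not account for the loss of these calls. The fry test, which asks whether a group moves on balance without setting it against other probes, passed 18, 12 of them among the 16. Those of the 16 that did not pass fry included the histone and ribosomal shifts at 3 h light against 7.5 h dark (adjusted p of 0.439 and 0.0961). The others were GAPDH after lights off (0.096) and the histones in light against dark (0.442). The chaperone, membrane transport, redox, signalling, ubiquitin and translation groups passed camera in 0 of their comparisons, the nearest being translation at 3 h light against 7.5 h dark (mean 0.15, adjusted p of 0.0707). Of the 16 shifts 9 lost their call with quantile normalisation and the same 9 in the authors' table, and none reversed under quantile normalisation, normexp, the authors' table or spike-in scaling.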

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

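The tests of the slide sets, of elapsed time and of scan day were chosen after the results they bear on had been seen, and so was the requirement that the bound for a culture ahead in the cycle be met by more than its error; the other tests were set before.

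More probes passed 0.5 h after lights on (4848) than 0.5 h after lights off (57), and the light minus dark difference at dawn differed from that at dusk in 1300 of 42991 probes by a limma test of the difference itself, 339 higher and 961 lower at dawn. A difference between the slide sets would return after lights off with its sign turned, but over the 4848 probes the median ratio was 0.083 (quartiles -0.0642 and 0.227), and 5.96% of the probes reached a ratio of 0.5. The time elapsed between harvests would make 6 h light differ from 3 h light in the same way, but the median ratio was 0.0143 (quartiles -0.176 and 0.186), although that pair also differs by 3 h of the cycle, and 5.34% reached 0.5. A course of the dark period that simply continued would give the same sign between 0.5 and 4 h dark, but 43.1% of the probes had it (42.2% and 44.1% in the replicates; 44.7% over all probes). Whether a response to light, a clock of the cells or a course that began late in the dark underlay the difference was not tested, and all 3 stay open.

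Replicate 1 differed from replicate 2 in a similar way at all time points, with a median correlation of the differences of 0.639 over the 28 pairs of time points. All arrays of a replicate number were scanned on the same day and on slides of their own, so scan day, slide and culture cannot be told apart. If a culture had run ahead in the cycle, what remained of the difference at each time point would follow the slope of the probes' courses. The median correlation with that slope was 0.0754, with 6 of 8 time points of its sign. It lay within the bound set in advance by less than its error (SE 0.0881; values from -0.199 to 0.566), so this explanation stays open.

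Spike-in control spots, which entered none of the comparisons as made at first, carried signal above the negative controls (median 1910 over 320 spots against 5.76 over 153), and relative to the 75th percentile of the probes they ran from -1.18 on the log2 scale in 0.5 h dark replicate 2 to 0.639 in 3 h light replicate 1.

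The count of probes between light and dark was set against other splits. Of the 56 ways to pick 5 of the 8 time points 6 gave at least the 16564 probes of the real pick. A count of that size was thus not particular to light against dark. The other picks also set apart time points that differed over the cycle. They therefore do not measure what chance alone would give. The highest other, 22982, set 0.5 and 15.5 h light and the dark time points against the rest, which points to a structure of the samples other than light and dark. With the replicate block 5 of the 56 picks gave at least the real 23267 probes (highest other 28371, the same pick), with the same limit. With time points as replicates, 3 of 100 splits of the 16 arrays gave at least the real 1901 probes (highest other 4120). Each of the 99 other splits parted the arrays of at least 2 time points, which the real split keeps together, so this count does not bear on chance.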

How the results depend on the processing

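Scaling on the spike-in spots was chosen after the data had been seen; the other alternatives had been set in advance. The brightest probe per gene was not run, because the probes carry no gene names, and a fixed slide block could not be fitted where groups lay on different slides. Reversal was assessed only for the 16 group shifts and the 4 probes named by number, and none of these reversed. Some medians over all probes changed sign. With spike-in scaling the median went from -0.02 to 0.49 for 0.5 h light against 7.5 h dark. It went from 0.01 to -0.83 for 7.5 h against 0.5 h dark. For 3 h light against 7.5 h dark and for light against dark the median stayed negative under each scaling. Probes peaking at 3 h light went from 2454 to 31 with spike-in scaling. The 4 probes named by number kept direction and call in each alternative that held them, with smaller changes in normexp and the authors' table; the strict filter on dim probes held 2. No filter, the strict filter and the variance prior with trend moved no count by over 1.5 times. At least 95.82% of the probes were well above background on each array, but results still moved with normexp. The count for 0.5 h dark against 15.5 h light went from 57 to 156. Probes peaking at 15.5 h light went from 2589 to 4598. For the counts below the cause was not tested, except that a further threshold leaves fewer calls by construction.

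With the replicate block, counts were 15132 (3 h light against 7.5 h dark), 10183 (0.5 h light against 7.5 h dark), 254 (0.5 h dark against 15.5 h light) and 10915 (7.5 h against 0.5 h dark). It gave 33054 over the cycle, 16204 for 15.5 h against 0.5 h light and 23267 for light against dark. With the block 3 group shifts were lost and 1 was gained; it changed the call of no other group shift and of none of the 4 probes named by number. The number of single probes called differed in 36 of the 72 group comparisons, with 208 calls in all in place of 134. With the slide as a random block they were 15768 for 3 h light against 7.5 h dark, 16567 for 15.5 h against 0.5 h light, 27 for 0.5 h dark against 15.5 h light, 11296 for 7.5 h against 0.5 h dark and 8804 for light against dark. As a fixed block it gave 16441 for 3 h light against 7.5 h dark, 17293 for 15.5 h against 0.5 h light and 11812 for 7.5 h against 0.5 h dark. The arrays compared alone gave 1678 for 0.5 h light against 7.5 h dark and 5922 for 15.5 h against 0.5 h light. For 0.5 h dark against 15.5 h light they gave 0 (limma, 2087 at an unadjusted p below 0.05). Light against dark gave 3762 at a fold change of at least 2, and 1901 in 2 groups with time points as replicates. Normexp gave 156 for 0.5 h dark against 15.5 h light. Group shifts, 16 in the model as reported, numbered 9 with quantile normalisation, 9 in the authors' table and 0 with an estimated correlation (camera, 6 of 72 at an unadjusted p below 0.05).

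Spike-in scaling gave 14252 probes over the cycle. It gave 1509 and 1073 for 3 h and 0.5 h light against 7.5 h dark, 4208 for 15.5 h against 0.5 h light and 4030 for 7.5 h against 0.5 h dark. It gave 6761 for light against dark, 10 group shifts, and 0 for 0.5 h dark against 15.5 h light (limma, 520 at an unadjusted p below 0.05).

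Without single arrays, counts ran from 2505 to 10947 for 3 h light against 7.5 h dark, 1890 to 6153 for 0.5 h light against 7.5 h dark and 2625 to 7592 for 7.5 h against 0.5 h dark. Group shifts ran from 9 to 18; each of these was lowest without replicate 1 of 7.5 h dark. For 15.5 h against 0.5 h light the range was 6657 (without replicate 1 of 15.5 h light) to 12614. For 0.5 h dark against 15.5 h light it was 3 (without replicate 2 of either group) to 78. A lone array left in a group was assumed to vary like the other groups.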

Other observations

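The values in this part were picked after they had been seen and were not recomputed under the alternatives, except that the time points of the highest and lowest means named here were the same under each scaling.

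Some signatures of carbon metabolism had too few probes for a test as a group. Each dehydrogenase signature below rested on 1 forward hit. Both probes with the signature of fructose or sedoheptulose bisphosphatase, enzymes of carbon fixation and sugar synthesis, changed over the cycle (limma F-test). Their mean was highest at 0.5 h light (0.98 on the log2 scale relative to the cycle mean) and lowest at 15.5 h light (-1.40). From 0.5 to 15.5 h light 1 of the 2 fell by 4.27 (limma, adjusted p of 4.85e-05), and the other had a change of -0.50. Through the dark period 1 rose by 2.86 (adjusted p of 0.00141), and the other had a change of 0.16. The probe of isocitrate or isopropylmalate dehydrogenase, enzymes of the citric acid cycle and of leucine synthesis, was highest at 0.5 h dark (0.70) and lower in the light than in the dark, with a change of -0.55 (adjusted p of 0.00873). The probe of acyl-CoA dehydrogenase, an enzyme of fatty acid breakdown, did not pass the F-test (range 0.45).

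Probes of some other signatures went separate ways. At 3 h light against 7.5 h dark the 9 probes with the DnaJ domain of chaperone partners had changes from -1.49 to 4.27, with 1 called higher and 2 lower. The probe with the end shared by cytosolic HSP70 and HSP90 chaperones rose by 1.97 (adjusted p of 0.00438; 2.24 and 1.70 in replicates 1 and 2). Across the light period the 3 mitochondrial carrier probes had changes from -1.86 to 2.39, with 1 rising and 1 falling. Of 4 thioredoxin probes, 2 were higher in the light than in the dark.

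Over all pairs of time points, the counts of differing probes (limma, adjusted p below 0.05) ran from 57 between 15.5 h light and 0.5 h dark to 17041 between 6 h light and 0.5 h dark. There were 222 between 4 and 7.5 h dark and 293 between 3 and 6 h light, although 3 h light was harvested in the following light period and lay on other slides.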
